A study of Mus musculus with 8 samples.

How the data were processed

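Gene expression was measured on Affymetrix mouse arrays in epithelial cells of intestinal crypts, sorted by flow cytometry. Per the labels' protocols, cells were freed from mouse intestine with EDTA, Dispase and DNase, and sorted by surface EphB2 (high, medium or low) or by green fluorescence from a reporter knocked into the Lgr5 gene (high or low). The same protocols say that total RNA was extracted with Trizol and amplified isothermally before hybridization. The EphB2 groups held 2 arrays each and the Lgr5 groups 1 array each, 8 arrays in all.

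Per the submitters' processing notes, RMA (background correction, quantile normalization and summary over a probe set) made the deposited log2 values; its version was not given in the sources used here. The deposited table held 45101 probe sets per array, with array medians between 6.12 and 6.20 on the log2 scale. Whether the 8 arrays were normalized together is not given in the sources used here. RMA forces nearly equal distributions on the arrays, so a change in total RNA per cell cannot be seen. For arrays, the number of samples limits the precision.

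Probe sets were named through a table of platform annotation. Of the probe sets, 34945 named 1 gene, 932 named several, and 9160 had no name in the table used. A further 64 control probe sets were left out of every test. The gene ID of 34741 of the single-gene probe sets was found in the RefSeq gene table used. Each of 18193 genes was represented by its brightest single-gene probe set over the 6 EphB2 arrays. Of the 199 genes the named-gene rule gave, 101 had further probe sets, and in 10 of these another probe set had the opposite sign of difference between EphB2 high and low, each with an unadjusted p above 0.05. Ephb2 itself had no single-gene probe set and was not analysed here. The same held for several list members, among them 10 of the 19 Paneth cell genes, most of which belong to the near-identical defensin family.

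The main test was limma (version 3.58.1, in R 4.3.3; lmFit, contrasts.fit and eBayes, 2-sided) on the 6 EphB2 arrays with group as the only term, which left 3 residual degrees of freedom. Benjamini-Hochberg adjustment ran over all 18193 genes, and a call needed an adjusted p below 0.05. No dim probe set was removed. Errors given with log2 differences are limma's standard errors, with 2 arrays per group. The labels do not say whether replicates came from separate animals, so p-values measure the spread between these samples, which may be technical.

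Each EphB2 replicate number marks a shared hybridization in the labels. Samples with the same number therefore form pairs, here called the first and second hybridization. The Lgr5 arrays formed a separate hybridization of their own. Across genes, deviations from the group means of same-numbered arrays correlated at 0.45 for high and medium, 0.13 for high and low, and 0.21 for medium and low. A fit with the number as a block was planned as an alternative, because no source says the study used one.

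Before the data were examined, 23 gene lists, the rule for named genes and the alternatives were fixed. The lists were markers of crypt, secretory, absorptive, immune, stromal and red blood cells, and pathway lists. Of these, 22 had the 5 measured members that a test required. Shifts were tested with limma's camera at its preset inter-gene correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and fry, which tests whether a list's genes move on balance one way, were alternatives. The estimated correlation called 0 of 22 lists in every EphB2 comparison. The lists it did not call included the enterocyte list, of which 28 of 29 genes fell between high and low. Calls under it therefore do not tell lists apart, though camera's unadjusted p with it was lowest for that list there (0.0184). The correlations it estimated were 0.94 for mitosis, 0.86 for replication, 0.69 for ribosome biogenesis and 0.68 for stem cell genes. These lie far above the preset 0.01, so camera's p-values at the preset may be much too small for such lists. The stem cell and Wnt target lists share 9 genes. Several lists come from general knowledge of the crypt that partly rests on published arrays of sorted crypt cells. The stem cell list may include genes that the study chose on these samples, so it is not independent evidence of its own direction.

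The named-gene rule took the Lgr5 sort marker and the 15 genes of largest log2 difference in each direction between EphB2 high and low. It took 8 in each direction for the other EphB2 comparisons, all among called genes whose arrays did not overlap. For the Lgr5 comparison it took 10 in each direction among genes whose brighter array was above the median of all genes. Per list, up to 5 members with the smallest p were taken, or with the largest difference in the Lgr5 comparison. Names without an assigned function were skipped, 1 in each direction between EphB2 high and medium and 1 of the higher genes in the Lgr5 comparison.

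With 1 array per Lgr5 group, no p-value was computed. Instead, each list's median difference was placed as a percentile among 10000 random lists of equal size matched on mean expression. The share of called genes with the same sign in both sorts and the place of the medium group between high and low are descriptions. Genes are not independent replicates.

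The alternatives were the block (fixed or random), a filter on dim genes, other rules for choosing a probe set, further scaling of the arrays, other eBayes settings, a 2-fold minimum, each hybridization alone, and leaving out each array in turn. In simulated data for the comparison of EphB2 high and low, 200 of 18193 genes were changed. Limma recovered 40% of the 100 genes changed by 1 log2 unit and 84% of the 100 changed by 2, with 7 false calls. The real comparison called 6792 genes, and the simulated noise held no hybridization effect. These rates therefore do not give the recovery or false calls in the real data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.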

Results

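Expression was compared along the axis of the mouse intestinal crypt with a pair of sort markers. EphB2 is a receptor tyrosine kinase whose surface level is highest at the crypt base and falls towards the villus, and Lgr5 is a receptor for R-spondins that marks cycling stem cells at the base. The EphB2 sort gave 2 arrays each of high, medium and low cells, and the Lgr5 reporter sort gave 1 array each of high and low cells. The first principal component over genes held 71.6% of the variance of the 8 arrays. On it the EphB2 high arrays lay at -41.2 and -49.5, the medium arrays at -3.10 and -6.23, and the low arrays at 70.7 and 90.3. The Lgr5 high array lay at -60.8 and the Lgr5 low array at -0.21.

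**Figure D1:**
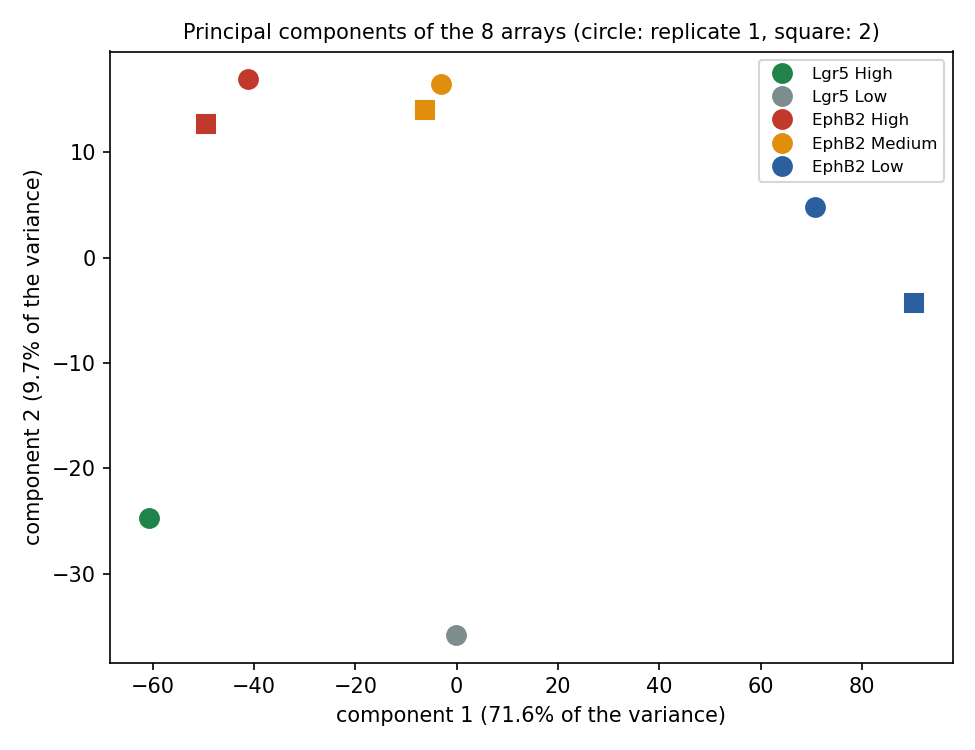
Scores of the 8 arrays on the first (horizontal) and second (vertical) principal component of the log2 values, coloured by sorted group, with circles for replicate 1 and squares for replicate 2. The EphB2 groups follow the order high, medium, low on the first component, and the Lgr5 low array (-0.21) is near the EphB2 medium arrays there, while on the second component the Lgr5 arrays (-24.7 and -35.8) lie apart from all EphB2 arrays.

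The comparison of EphB2 high with EphB2 low cells asks which genes mark the base of the crypt. Lgr5 was higher by 4.25 ± 0.25 (log2, SE, n = 2 arrays per group; 19.0-fold; limma adjusted p = 0.000294). Ascl2, a transcription factor of intestinal stem cells, was higher by 3.98 ± 0.16 (adjusted p = 0.000142), and the secreted growth factor-binding protein Igfbp4 by 3.81 ± 0.16 (adjusted p = 0.000151). In the other direction, the sodium-coupled transporter Slc5a12 fell by 6.54 on the log2 scale (SE 0.36, adjusted p = 0.000247) and the glucose-6-phosphatase gene G6pc fell by 6.27 (SE 0.36, adjusted p = 0.000283). In all, 6792 of 18193 genes differed, 4010 of them higher and 2782 lower in EphB2 high cells, and 3374 differed at least 2-fold.

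Among the 15 genes of largest rise were Tnfrsf19 (4.74 ± 0.70) and Cyp2e1, a cytochrome P450 enzyme (4.73 ± 0.29). The group also held Ripor2 (4.44 ± 0.41), the receptor phosphatase Ptpro (4.14 ± 0.22), Prelp (4.06 ± 0.41) and the noncoding RNA Pvt1 (4.05 ± 0.22). Further members were the amino acid transporter Slc38a4 (3.98 ± 0.35), the protocadherin Pcdh8 (3.95 ± 0.21), Rgs13 (3.94 ± 0.50), the RNA-binding protein Mex3a (3.81 ± 0.26), Bex4 (3.78 ± 0.36) and the urea transporter Slc14a1 (3.77 ± 0.38). Among the 15 genes of largest fall, besides Slc5a12 and G6pc, the neutral amino acid transporter Slc6a19 fell by 5.64 (SE 0.30), the dicarboxylate transporter Slc13a2 by 5.70 (SE 0.29), Slc5a4b by 5.70 (SE 0.42), and Cubn, the receptor for vitamin B12 bound to intrinsic factor, by 6.02 (SE 0.60). The others were Bst1, Saa1, Cyp2b10, Plb1, Gdpd2, Cyp3a11, Ido1, Synpo and Ceacam20, with differences between -6.12 (Bst1) and -5.68 (Ceacam20). All 30 kept their call with the hybridization as a block. Leaving out 1 array moved 6 of them by over 1.5-fold. Without EphB2 Low replicate 1 and 2 in turn, Tnfrsf19 was at 5.87 and 3.61 and Prelp at 4.71 and 3.41. Without EphB2 High replicate 1 and 2 in turn, Bst1 was at -5.37 and -6.88, Plb1 at -5.49 and -6.69, Cubn at -5.02 and -7.01 and Cyp3a11 at -4.83 and -7.14.

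All 22 measured stem cell genes rose, with a median difference of 2.61, and 22 passed when adjusted over the list alone. With the block 21 rose, and Ptk7, named after its value was seen, did not pass (adjusted p = 0.0571). This list may include genes chosen on these samples and is not independent evidence of its direction. The Eph receptor Ephb3 rose by 2.84 ± 0.15 and the repulsive guidance molecule Rgmb by 2.10 ± 0.13. The list shifted as a whole (camera, adjusted p = 1.12e-11; adjusted p = 0.519 with an estimated correlation). Of 8 reserve stem cell genes, named for slowly cycling cells, 6 rose and 2 did not pass, with 6 adjusted over the list alone. Mex3a and the EGF receptor inhibitor Lrig1 (1.66 ± 0.15) were among them, and so was Bmi1 (0.92 ± 0.13). The shift had an adjusted p = 0.00543, and adjusted p = 0.519 with an estimated correlation. Of 18 Wnt target genes, 15 rose and 3 did not pass, with a median of 1.76; adjusted over the list alone, 15 were higher and 1 lower. The transcription factor Sox9 rose by 1.56 ± 0.12 and the ubiquitin ligase Rnf43, which limits Wnt signalling, by 1.56 ± 0.13. The shift had an adjusted p = 1.22e-05, and adjusted p = 0.519 with an estimated correlation. This list shares 9 genes with the stem cell list, so it is not fully independent evidence either.

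Cell cycle and growth genes moved with them. All 29 mitosis genes rose (29 adjusted over the list alone; median 2.13), among them the spindle kinase Ttk (2.62 ± 0.23) and the kinesin Kif20a (2.81 ± 0.31). All 32 DNA replication genes rose (32 adjusted over the list alone; median 1.86), among them the helicase subunit Mcm2 (1.97 ± 0.23) and the ribonucleotide reductase subunit Rrm1 (2.01 ± 0.24). Of 26 ribosome biogenesis genes, 25 rose and 1 did not pass (25 adjusted over the list alone; median 1.39), among them Utp20 (1.81 ± 0.16) and the RNA polymerase I subunit Polr1b (1.97 ± 0.22). The camera adjusted p was 2.46e-11 for mitosis, 1.20e-11 for replication and 2.14e-10 for ribosome biogenesis. All 3 calls were lost, at adjusted p = 0.519 with an estimated correlation, a setting that called 0 of the 22 lists.

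Enterocyte genes fell. Of 29 measured, 28 fell, 0 rose and 1 did not pass, with a median of -2.77 and 28 lower when adjusted over the list alone. The lipid carrier Apoa4 fell by 4.04 (SE 0.11), the protease Mep1b by 3.59 (SE 0.11), the trehalase Treh by 4.17 (SE 0.13) and the fructose transporter Slc2a5 by 4.08 (SE 0.15). The camera adjusted p was 1.81e-18, and adjusted p = 0.405 with an estimated correlation. Of 16 fatty acid oxidation genes 7 fell and 9 did not pass (9 lower adjusted over the list alone), among them Acaa1a (-1.63 ± 0.11) and Ehhadh (-1.46 ± 0.17); the shift had an adjusted p = 0.00013, and adjusted p = 0.519 with an estimated correlation. Of 25 oxidative phosphorylation genes 3 fell, Sdhb (-0.38 ± 0.11), Ndufa1 (-0.48 ± 0.14) and Cycs (-0.36 ± 0.11), and limma called 0 when adjusted over the list alone (4 at an unadjusted p below 0.05). The calls of Sdhb and Cycs were lost whichever array was left out (adjusted p up to 0.184 and 0.208, each without EphB2 High replicate 2), and that of Ndufa1 whichever array but EphB2 High replicate 1 was left out (up to 0.205, without EphB2 High replicate 2). That list had a median of -0.13 and an adjusted p = 0.0237 (adjusted p = 0.519 with an estimated correlation), and its shift was lost without EphB2 High replicate 2 (0.0653), without EphB2 Low replicate 2 (0.0579) and with quantile normalization (0.0941; 0.00707 to 0.519 over all alternatives). Of 17 cholesterol synthesis genes 4 fell, led by Sc5d (-1.39 ± 0.17), and 3 were lower adjusted over the list alone; the list did not pass (adjusted p = 0.0587; 0.00909 without EphB2 Low replicate 1).

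**Figure D2:**
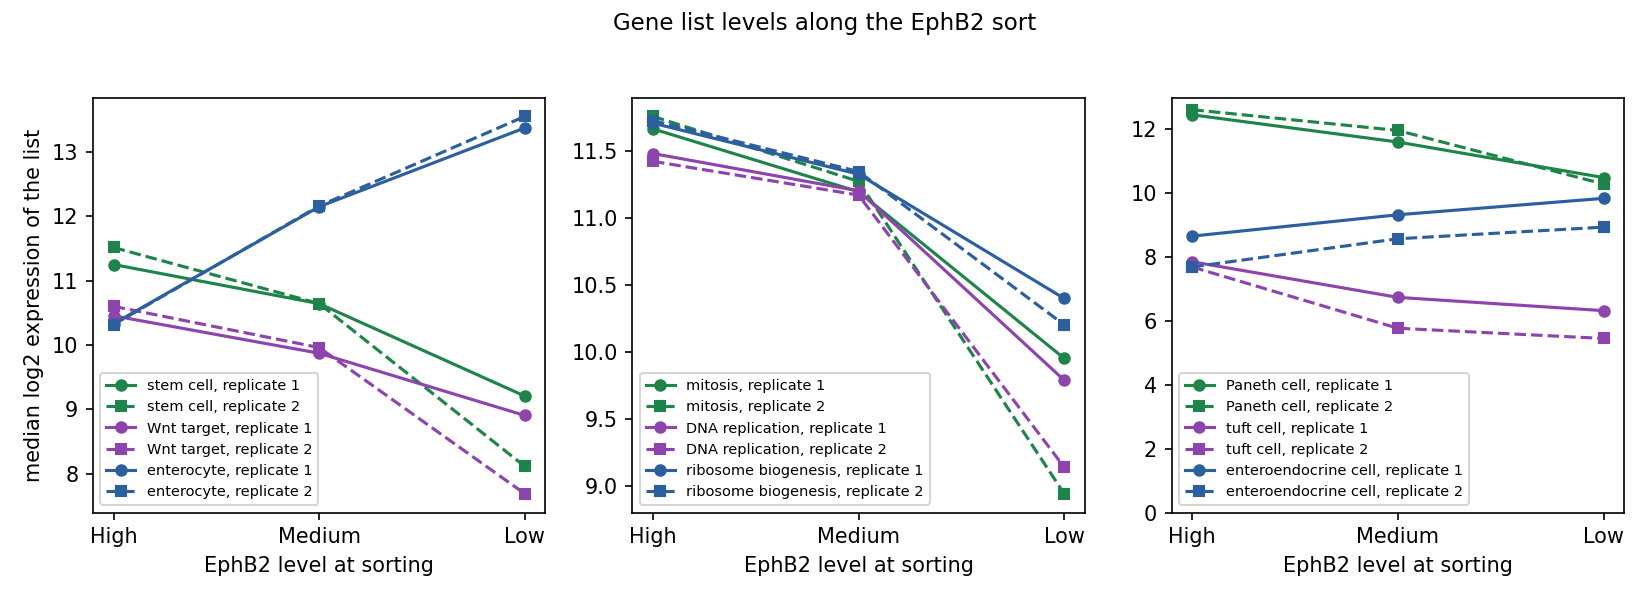
Median log2 expression of a list's measured genes (vertical) on each EphB2 array, ordered by EphB2 level at sorting (horizontal); solid lines with circles join the arrays of replicate 1 and dashed lines with squares those of replicate 2. The enterocyte medians go from 10.33 and 10.32 on the high arrays to 13.37 and 13.55 on the low arrays, and the mitosis medians from 11.67 and 11.76 to 9.95 and 8.94.

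Secretory cell markers moved in different directions. Of 9 measured Paneth cell genes 8 rose and 1 did not pass, with a median of 0.99 and 9 higher adjusted over the list alone. The protease Mmp7, which processes defensins, rose by 2.15 ± 0.17, and Wnt3, a ligand that Paneth cells supply, by 1.83 ± 0.24; the defensin Defa3 rose by 2.40 ± 0.22 on a probe set that near-identical family members can reach. The list shift had an adjusted p = 0.000378, and adjusted p = 0.519 with an estimated correlation. Of 14 tuft cell genes 7 rose, 1 fell and 6 did not pass, with a median of 1.14; adjusted over the list alone, 8 were higher and 1 lower. Dclk1, a kinase that marks tuft cells, rose by 3.36 ± 0.53, Alox5ap by 2.18 ± 0.40, and the leukotriene synthase Ltc4s fell by 1.03 (SE 0.19). The tuft shift had an adjusted p = 0.0237, and adjusted p = 0.54 with an estimated correlation; it was lost without EphB2 High replicate 1 (0.0515) and without EphB2 Low replicate 1 (0.0506), and fry gave 0.0708 (0.00247 to 0.54 over all alternatives).

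Of 20 enteroendocrine genes 6 fell, 1 rose and 13 did not pass, also when adjusted over the list alone, with a median of -0.97. The hormone genes Sct and Sst fell by 1.88 (SE 0.20) and 1.64 (SE 0.25), while Neurog3, the factor of early endocrine progenitors, rose by 1.22 ± 0.27. The call of Neurog3 was lost without EphB2 High replicate 1 (adjusted p = 0.0667), EphB2 High replicate 2 (0.0825) and EphB2 Low replicate 2 (0.064). The list shift had an adjusted p = 0.00893 (adjusted p = 0.588 with an estimated correlation) and was lost without EphB2 Low replicate 1 (0.133) and with fry (0.172; 0.000366 to 0.588 over all alternatives). With the block, 9 fell and 2 rose. Of 16 goblet cell genes 6 rose, 6 fell and 4 did not pass; adjusted over the list alone, 7 were higher and 6 lower. Retnlb, an antimicrobial protein, rose by 2.23 ± 0.26, and Fer1l6 fell by 2.58 (SE 0.26) and the chloride channel regulator Clca1 by 0.98 (SE 0.16). The goblet list did not shift (median 0.26, mean 0.07, adjusted p = 0.922).

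Of 19 Notch pathway genes 8 rose, 2 fell and 9 did not pass; adjusted over the list alone, 9 were higher and 2 lower. The receptor Notch1 rose by 2.85 ± 0.19 and the glycosyltransferase Lfng by 3.01 ± 0.25, and the Notch inhibitor Numb fell by 0.88 (SE 0.13). The list shift had an adjusted p = 0.0491 (adjusted p = 0.519 with an estimated correlation) and was lost with the block, at an adjusted p = 0.0705. It was also lost without either EphB2 Medium array (0.0536 for each), without EphB2 Low replicate 1 (0.0656) and without EphB2 High replicate 2 (0.0827), with quantile normalization (0.0558) and with the dim filter (0.181). Over all alternatives it ranged from 0.0145 to 0.519. Of 15 BMP pathway genes 2 rose and 4 fell, the same numbers as adjusted over the list alone. The ligand Bmp7 rose by 2.36 ± 0.13 and the ligand Bmp2 fell by 3.06 (SE 0.26); the list did not shift (adjusted p = 0.547). Of 17 Eph and ephrin genes 6 rose and 5 fell; adjusted over the list alone, 7 were higher and 5 lower. The receptor Epha4 rose by 2.89 ± 0.22 and the ligand Efna4 by 2.25 ± 0.15, while the ligand Efnb2 fell by 2.62 (SE 0.15) and the receptor Epha2 by 1.84 (SE 0.13). The Eph and ephrin list did not shift (adjusted p = 0.82), but with the dim filter it passed as lower in high cells (median -1.03, adjusted p = 0.0394; 0.0394 to 0.92 over its alternatives).

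For markers of cells from outside the epithelium, median levels per array ran from 4.22 to 4.99 for lymphocyte genes, from 3.84 to 4.68 for myeloid genes and from 4.30 to 4.66 for stromal and endothelial genes. Single members were brighter, with means over the EphB2 arrays of 9.999 for Lyz2, 9.81 for Vim and 8.95 for Cd14. Of 18 lymphocyte genes 1 rose and 4 fell, also when adjusted over the list alone, with Cd52 at -1.72 ± 0.16 and Cd79b at 0.99 ± 0.23; the call of Cd79b was lost without EphB2 High replicate 1 (adjusted p = 0.0808) and without EphB2 Low replicate 2 (0.0934). Of 14 myeloid genes 3 rose and 1 fell, also when adjusted over the list alone. Those that rose included the lipopolysaccharide co-receptor Cd14 (1.98 ± 0.22) and the lysozyme Lyz2 (0.65 ± 0.15). Lyz2 was lower in the Lgr5 high array (-1.35), as were the Paneth list (-0.43) and the myeloid gene C1qa (-1.34). This does not tell which cells the rise of Lyz2 marks. The call of Lyz2 was lost without EphB2 High replicate 1 (adjusted p = 0.0758), EphB2 Low replicate 1 (0.0786) and EphB2 High replicate 2 (0.0965). Of 17 stromal and endothelial genes 0 were called by limma, also when adjusted over the list alone (2 at an unadjusted p below 0.05). With the block, 2 fell, Vim (-1.14, adjusted p = 0.0079) and Col1a2 (-0.51, adjusted p = 0.0302). None of these 3 lists shifted (adjusted p = 0.15, 0.997 and 0.36), though the lymphocyte list passed without EphB2 Low replicate 2 (0.0431). For myeloid genes the median (0.01) and mean (0.16) were above 0 while camera ranked the list below other genes. Of 7 genes of MHC class II presentation 1 fell, the protease Ctss (-0.84 ± 0.11), also when adjusted over the list alone; the list did not shift (adjusted p = 0.126), but passed without EphB2 High replicate 1 (0.0434). Of 17 dissociation stress genes 2 rose and 3 fell, also when adjusted over the list alone. The chaperone Hsp90aa1 rose by 0.56 ± 0.10 and Junb fell by 0.46 (SE 0.11). The call of Hsp90aa1 was lost without either EphB2 High array (adjusted p = 0.0513 and 0.0519), and that of Junb without EphB2 High replicate 1 (0.085), EphB2 High replicate 2 (0.108) and EphB2 Low replicate 2 (0.0792). With the block 3 rose and 5 fell, and the list did not shift (median 0.11, mean -0.03, adjusted p = 0.841).

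When 1 array was left out, limma called between 4245 and 6160 genes between EphB2 high and low. The 4245 were without EphB2 High replicate 2, and 4183 of them were among the 6792; the 6160 were without EphB2 Low replicate 1, and 5650 of them were among the 6792. With the hybridization as a block it called 7463 genes, of which 6677 were shared with the 6792.

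EphB2 medium cells were next set against EphB2 low cells. Tnfrsf19 was higher in medium cells by 3.17 ± 0.70 (log2, SE, n = 2 arrays per group), Cyp2e1 by 3.03 ± 0.29 (limma adjusted p = 0.00329), Slc7a2, an arginine transporter, by 2.87 ± 0.31, and Dctd, a deaminase of nucleotide synthesis, by 2.77 ± 0.49. Ripor2 (2.93 ± 0.41), Slc38a4 (2.91 ± 0.35), Ccdc18 (2.82 ± 0.60) and Ptpro (2.76 ± 0.22) completed the higher group. The phospholipase Plb1 fell by 4.39 (SE 0.37), Susd2 by 4.36 (SE 0.20), the kinase Sgk2 by 4.12 (SE 0.39), Spsb4 by 4.01 (SE 0.27) and the myelin protein Pmp22 by 4.01 (SE 0.23). Ceacam20 fell as well (adjusted p = 0.000775), and Gdpd2 and Tmigd1 fell by 3.98 and 3.88. In total 4489 genes differed, 2656 higher and 1833 lower, and 2034 at least 2-fold.

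In this comparison 21 of 22 stem cell genes rose (21 adjusted over the list alone), 29 of 29 mitosis genes (29), 31 of 32 replication genes (32) and 24 of 26 ribosome biogenesis genes (25). Of 29 enterocyte genes 24 fell and 5 did not pass, with 25 lower adjusted over the list alone and a median of -1.23. Of 14 tuft genes limma called 0 higher (3 at an unadjusted p below 0.05) and 1 lower (Ltc4s, -1.30 ± 0.19), also when adjusted over the list alone; with the block 4 rose. Of 7 MHC class II genes 2 fell, and 3 were lower adjusted over the list alone; H2-Aa differed by -1.55 ± 0.32. That list had a camera adjusted p = 0.0109, and adjusted p = 0.516 with an estimated correlation. Its shift was also lost with fry (adjusted p = 0.0883). Its medians on the medium and low arrays were 11.20 and 11.50 in the first hybridization, and 10.18 and 11.79 in the second. The count of calls was 988 without EphB2 Medium replicate 2, where more were lower (581) than higher (407), 1662 without EphB2 Medium replicate 1 and 2485 without EphB2 Low replicate 2. Without EphB2 Medium replicate 1 and 2 in turn, the adjusted p was 0.106 and 0.0834 for Tnfrsf19, 0.0737 and 0.108 for Ccdc18, and 0.0542 and 0.0752 for Dctd. The call of Ripor2 was lost without EphB2 Medium replicate 2 (0.052), and that of Tmigd1 without EphB2 Medium replicate 1 (0.0645) and EphB2 Low replicate 2 (0.0748).

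Between EphB2 high and medium cells 248 genes differed, 39 higher and 209 lower in high cells. Ido1, an enzyme of tryptophan breakdown, fell by 4.49 (log2, SE 0.40, n = 2 arrays per group, limma adjusted p = 0.0153), the glucose transporter Slc2a2 by 3.30 (SE 0.30, adjusted p = 0.0153) and the lactase gene Lct by 2.91 (SE 0.30, adjusted p = 0.0197). G6pc, Cyp2b10, Slc5a12, Nat8f5 and Otop3 fell by 3.16, 3.14, 2.95, 2.75 and 2.73. The higher group held Pcdh8 (1.74 ± 0.21), Lgr5 (1.70 ± 0.25), Zik1 (1.69 ± 0.20), Kcnh8 (adjusted p = 0.0391), the keratin Krt31 (1.46 ± 0.11), the exchange factor Vav3 (1.43 ± 0.18), Ascl2 (1.39 ± 0.16) and Ccdc3 (1.39 ± 0.12). With the block, 12 of these 16 kept their call; Lgr5 (adjusted p = 0.0784), Zik1 (0.0559), Kcnh8 (0.0566) and Vav3 (0.0566) did not.

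Of 29 enterocyte genes 16 fell and 13 did not pass, with 23 lower adjusted over the list alone, including Apoa4 (-2.25 ± 0.11) and Mep1b (-2.15 ± 0.11). The list had an adjusted p = 5.26e-32, and adjusted p = 0.187 with an estimated correlation. Of 22 stem cell genes 5 rose (9 adjusted over the list alone, 3 with the block), and of 18 Wnt targets 4 (7 adjusted over the list alone). Of 14 tuft genes limma called 0 (7 at an unadjusted p below 0.05, 6 adjusted over the list alone, 4 with the block), with a median of 1.05; the list shifted at an adjusted p = 8.53e-06 (adjusted p = 0.468 with an estimated correlation). The goblet list shifted down (adjusted p = 0.0446; 0.117 with the block; adjusted p = 0.705 with an estimated correlation). Of the mitosis, replication and ribosome biogenesis genes, limma called 0, also when adjusted over each list alone (3, 0 and 2 at an unadjusted p below 0.05), and their median differences were 0.38, 0.21 and 0.28. As lists, mitosis and ribosome biogenesis genes shifted up (camera, adjusted p = 0.000663 and 0.000788; adjusted p = 0.705 and 0.701 with an estimated correlation), and replication genes did not pass (0.0694). The dissociation stress list shifted down in high cells (median -0.22, adjusted p = 0.000771; adjusted p = 0.468 with an estimated correlation). Camera called 14 of 22 lists in this comparison, and 0 with an estimated correlation (1 at an unadjusted p below 0.05). Fry called 1, the enterocyte list (adjusted p = 0.00246). The mitosis, ribosome biogenesis, tuft and dissociation stress shifts were lost with fry (adjusted p = 0.556, 0.431, 0.134 and 0.112). For the Eph and ephrin, lymphocyte, myeloid, and stromal and endothelial lists the median and mean differed in sign and lay near 0, the farthest being the median of the Eph and ephrin list (0.05). No gene was called without EphB2 Medium replicate 1 or without EphB2 Medium replicate 2, where 1815 and 1892 genes had an unadjusted p below 0.05. The count was 32, with 0 higher, without EphB2 High replicate 2, 76 without EphB2 High replicate 1 and 101 without either EphB2 Low array. Of the 16 genes named first, Slc2a2 kept its call whichever EphB2 High or Low array was left out; the others lost theirs without at least 1 of them, with the highest adjusted p for Lgr5 (0.288, without EphB2 High replicate 2).

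For the place of the medium cells, the difference between medium and low was divided by that between high and low for each of the 6792 genes. The median was 0.71 (quartiles 0.58 and 0.82), and for 6352 genes (93.5%) the medium mean lay between the others. By list, over members called between high and low, medium cells held 88.6% of the difference for DNA replication genes (32 genes; 82.9% and 92.8% in the first and second hybridization). The figure was 81.7% for mitosis genes (76.2% and 84.4%) and 70.0% for stem cell genes (71.2% and 69.0%). It was 44.7% for enterocyte genes (44.8% and 46.7%) and 28.0% for 8 tuft genes (35.3% and 24.4%). These differences between lists were not tested.

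The Lgr5 sort used another marker and did not repeat the comparison of EphB2 high with low. On the first principal component its low array (-0.21) lay near the EphB2 medium arrays (-3.10 and -6.23). Its mitosis median (11.18) was also near theirs (11.20 and 11.27), against 9.95 and 8.94 on the EphB2 low arrays. Not every list did so, with a Paneth median of 12.98 against 11.61 and 11.97 on the medium arrays. Between the Lgr5 high and Lgr5 low arrays, with no replicate and so no test, Lgr5 was higher by 4.39 (log2), Tnfrsf19 by 3.55, Slc38a4 by 2.98, the secreted glycoprotein Fstl1 by 2.94 and Ccdc3 by 2.79. Cyria, the transcriptional coactivator Wwtr1, Bex4, the pepsinogen Pgc and Ripor2 followed with 2.57, 2.48, 2.44, 2.31 and 2.24. The drug-metabolizing enzyme Cyp3a11 differed by -6.63, the incretin hormone gene Gip by -6.42, Lct by -6.05, Bst1 by -5.90 and the peptide transporter Slc15a1 by -5.64. Saa1, Slc5a4a, Slc13a2, Dpep1 and Pmp22 followed with -5.62, -5.53, -5.49, -5.37 and -5.29. At least 2-fold differences numbered 1348, 425 of them higher and 923 lower in the Lgr5 high array.

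All 22 stem cell genes were higher in the Lgr5 high array (median 0.96, percentile 100 among random lists), and so were 16 of 18 Wnt targets (0.84, percentile 100), 29 of 29 mitosis genes (0.31, percentile 100), 27 of 32 replication genes (0.23, percentile 99.99) and 23 of 26 ribosome biogenesis genes (0.19, percentile 99.95). Reserve stem cell genes had a median of 0.42 (percentile 99.7). All 29 enterocyte genes (median -2.56) and all 20 enteroendocrine genes (median -2.05) were lower, both at percentile 0. Goblet genes had a median of -1.36 (percentile 0), tuft genes -0.71 (percentile 0.02), Paneth genes -0.43 (percentile 0.28), cholesterol synthesis genes -0.57 (percentile 0), fatty acid oxidation genes -0.28 (percentile 0.38) and oxidative phosphorylation genes -0.15 (percentile 6.87). Stromal and endothelial genes had a median of -0.37 (percentile 0.3), dissociation stress genes -0.26 (percentile 0.57) and MHC class II genes 0.37 (percentile 99.9). Lymphocyte, myeloid, Notch, BMP and Eph and ephrin genes lay between percentiles 29.4 and 62.4. Random lists do not allow for genes that move together, so an extreme percentile from 1 array per group is not a test. The mitosis, replication and ribosome biogenesis medians were near the median absolute difference between the Lgr5 arrays (0.235).

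**Figure D3:**
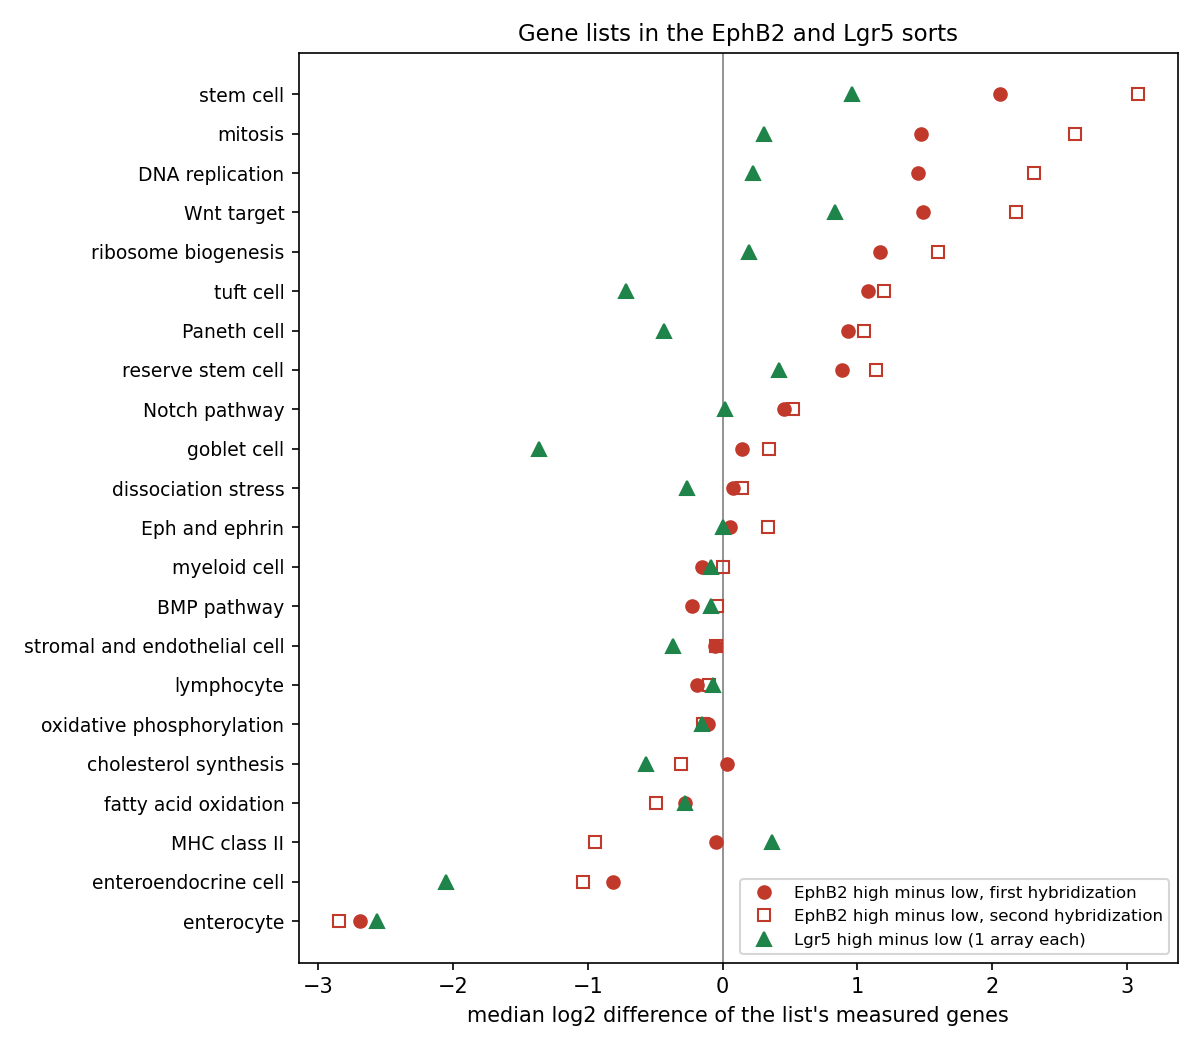
Median log2 difference (horizontal) of each gene list (vertical) between EphB2 high and low cells in the first (filled circle) and second (open square) hybridization, and between the Lgr5 high and low arrays (triangle). The enterocyte medians are -2.69, -2.85 and -2.56, while tuft cell genes are at 1.08 and 1.20 in the EphB2 sort and at -0.71 in the Lgr5 sort.

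Of the 6792 genes called between EphB2 high and low, 5908 (87.0%) had the same sign in the Lgr5 sort, 85.2% of those higher and 89.6% of those lower. Among genes not called the share was 61.1%. Across all 18193 genes, which are not independent replicates, the differences in the 2 sorts correlated at 0.69 (Pearson) and 0.61 (Spearman). The Lgr5 arrays were hybridized apart from the EphB2 arrays, so the difference in level between Lgr5 and EphB2 arrays cannot be told apart from the hybridization.

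**Figure D4:**
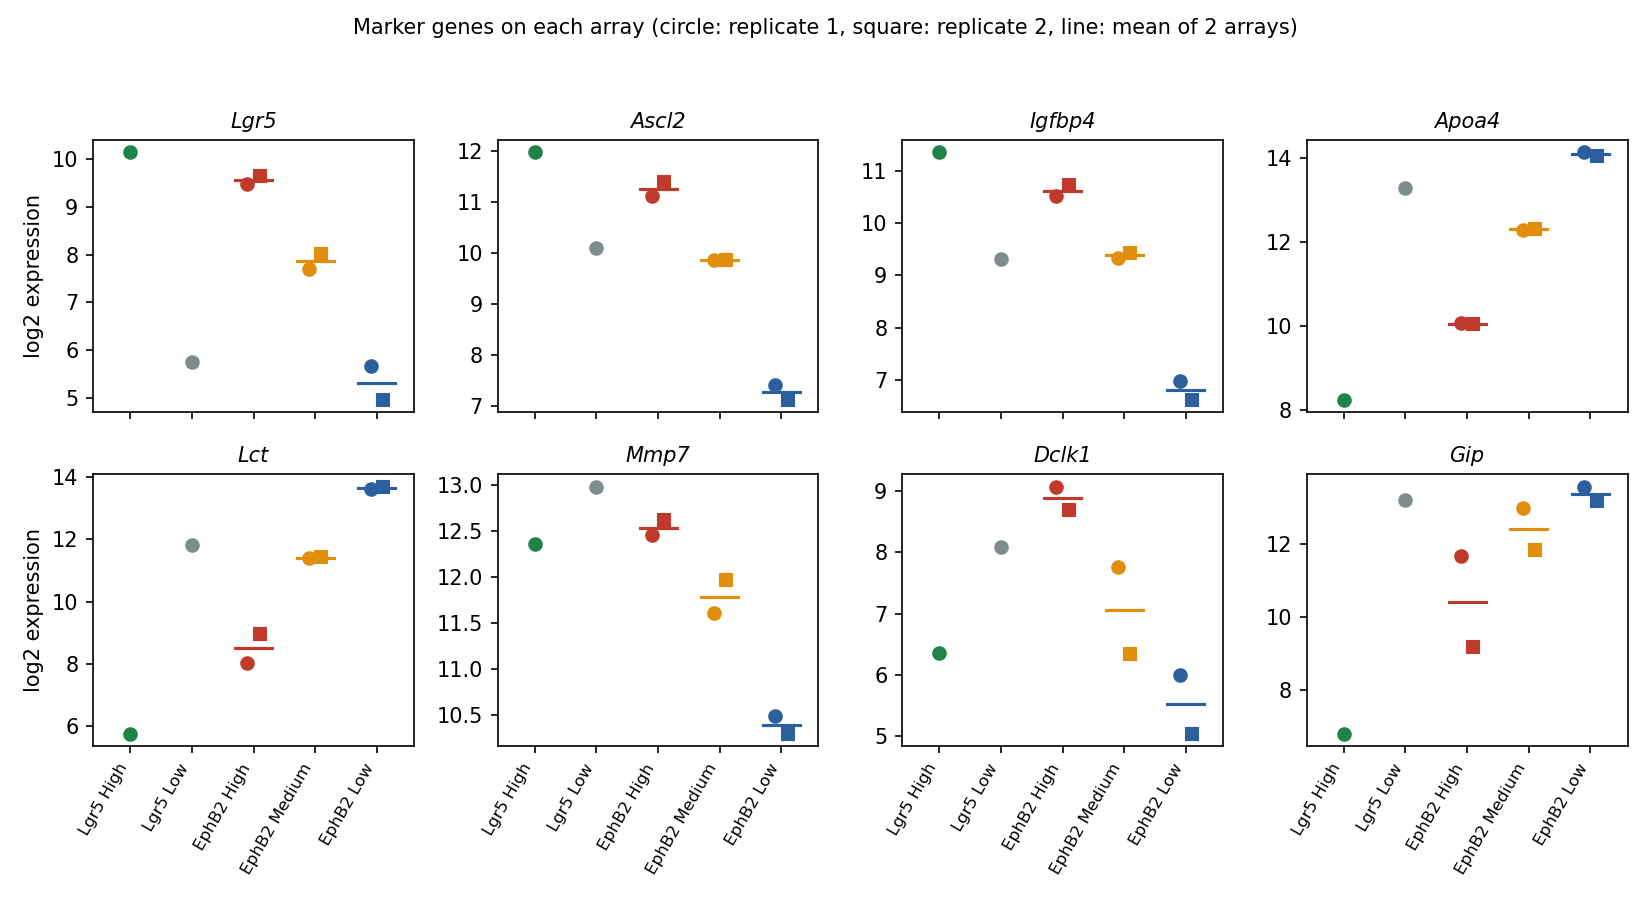
Log2 expression (vertical) of 8 genes on each array, by sorted group (horizontal), with circles for replicate 1, squares for replicate 2 and a line at the mean of 2 arrays. Lgr5 and Ascl2 are highest in the high groups of both sorts, and Dclk1 is higher in EphB2 high than low cells (3.36) but lower in the Lgr5 high than low array (-1.74).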

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

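The tests of explanations in this part were chosen after the result was seen. In the first cases that follow, the high minus low difference had one sign in both EphB2 hybridizations and the opposite sign in the Lgr5 sort; the difference between the sorts was not tested, because each Lgr5 group has 1 array.

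The Paneth cell list (Lgr5 high minus low median -0.43) and the tuft cell list (-0.71) were higher in EphB2 high than low cells (0.93 and 1.05 for Paneth, 1.08 and 1.20 for tuft genes). Cross-hybridization between near-identical family members is argued against by the 5 Paneth genes outside multigene families, whose Lgr5 median was -0.53 and whose EphB2 medians were 1.13 and 1.22. A distortion of the Lgr5 arrays set by brightness alone is argued against by the matched random lists, among which the higher of the Paneth and tuft percentiles was 0.28. These lists were picked for their negative Lgr5 medians, and random lists do not allow for genes that move together. The dim stromal and endothelial list reached percentile 0.3 as well, so other distortions stay open. Whether the markers gather different shares of Paneth and tuft cells may be asked only with more than the 1 array per Lgr5 group, so it stays open beside the separate hybridization and mice. The Lgr5 low array had a Paneth median of 12.98, against 10.49 and 10.29 on the EphB2 low arrays and 11.61 and 11.97 on the medium arrays. The high groups lay at 12.36 (Lgr5), 12.46 and 12.62 (EphB2).

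Other lists with opposite signs were goblet cell (Lgr5 median -1.36; EphB2 medians 0.15 and 0.34), dissociation stress (-0.26; 0.076 and 0.14) and MHC class II (0.37; -0.047 and -0.95). None of these 3 shifted between EphB2 high and low (camera, adjusted p = 0.922, 0.841 and 0.126), so the EphB2 sign is uncertain for them. The Lgr5 low array lay near the EphB2 medium arrays on the first principal component. Between EphB2 high and medium cells these lists had the Lgr5 sign (medians goblet -0.095, dissociation stress -0.22, MHC class II 0.42). The Paneth (0.27) and tuft (1.05) medians there still had the opposite sign. Among 199 named genes 30 were opposite, 22 of them called between EphB2 high and low. Tuft and secretory genes lower in the Lgr5 high array were Dclk1 (-1.74), Retnlb (-1.72), Gfi1 (-1.54), Rgs13 (-1.38), Sh2d6 (-1.27), Atoh1 (-1.22), Neurog3 (-1.15), Alox5ap (-1.15), Avil (-1.12) and Il25 (-0.45). Paneth genes lower there were Copz2 (-0.92), Mmp7 (-0.62), Ang4 (-0.53), Habp2 (-0.53), Itln1 (-0.43), Wnt3 (-0.40) and Cd24a (-0.042). The rest were Lyz2 (-1.35), Tert (-0.53), Hspa1a (-0.47), Cd79b (-0.30), Kcnh8 (-0.34), Ier2 (-0.10), Hsp90aa1 (-0.038), Gzma (3.005), H2-DMa (0.71), Cd2 (0.67), Ccl5 (0.46), H2-Ab1 (0.37) and H2-Aa (0.28). The values of Cd24a and Hsp90aa1 lie above the median of all genes in that sort (-0.050), so their signs depend on how the arrays are scaled, and the median absolute difference between the Lgr5 arrays was 0.235.

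A signal appeared in control probe sets that no comparison used. A control for a transcript not added to these samples, from a bacterial tryptophan gene, read 14.73 on the Lgr5 arrays and 3.41 on the EphB2 arrays. The last 10 control probe sets of the table differed by up to 11.32 between the 2 sets of arrays. Moving the Lgr5 values back by 1 place left a largest difference of 0.38, so a displacement within the table is a likely source. A real change is argued against by Tfrc: the Lgr5 minus EphB2 differences of its 3 control probe sets were -2.62, 1.62 and -6.75, against -0.16 in the gene's regular one. For the control of the middle of the transcript (-6.75), the control minus the regular probe set was -6.59. Among the other probe sets, 0 stretches of 10 that differed by over 1 on average came closer to the EphB2 means by at least a factor of 2 when moved by 1 place, and controls entered no test.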

How the results depend on the processing

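The alternatives were fixed before the data were examined. The exception is the spread used for the share of genes with the same sign. Each hybridization alone gave the same share, because the genes called on both have the same sign in each by selection. That says nothing about stability, so a binomial interval of the share was taken after seeing the data. The interval treats genes as independent, which they are not, so it does not measure stability either. With the replicate block, which pairs samples of 1 hybridization, calls numbered 7463 (high against low), 5082 (medium against low) and 221 (high against medium). Of 13 list shifts between high and low, the block ended only that of the Notch list (adjusted p = 0.0705). Beyond the calls given in the results with their blocked values, it ended that of Cd3d and added those of Ang4, Tac1, Sh2d6 and Hspa1a among named genes between high and low.

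A 2-fold minimum left 3374 calls (high against low) and 2034 (medium against low). High against medium moved from 248 to 406 with the block as a random effect, 456 with the dim filter, 626 with the replicate block and the dim filter, 135 with the probe set of largest variance and 506 with an intensity trend; the cause was not tested, except that the filter tests fewer genes. Between high and low, camera with an estimated correlation called 0 of 22 lists (1 at an unadjusted p below 0.05), against 13. Because it called none, its calls do not tell lists apart, though its lowest unadjusted p was for the enterocyte list (0.0184). Fry and the other settings that kept all arrays called between 11 and 13 there. The Lgr5 comparison had 569 genes of at least 2-fold difference with the dim filter, which removes genes, 86 higher and 483 lower (15.1% higher, against 31.5%). With genes called under the block, the same-sign share was 85.5%.

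Leaving out 1 array gave 4245 to 6160 calls (high against low), 988 to 4199 (medium against low) and 0 to 101 (high against medium). The group of the missing array then has 1 sample, assumed to vary like the others, and fewer degrees of freedom. The same-sign share ran from 86.7 to 90.8% and the median place of medium cells from 0.67 to 0.75. Cyp51 reversed, from -0.65 to 0.31, with the probe set of largest variance (adjusted p = 0.619; across its alternatives the adjusted p ranged from 0.00808 to 0.619); the cause was not tested. Among 231 results of named genes in the EphB2 comparisons, 199 values under an alternative lost the call, 50 gained it and 3268 kept their direction and side of the threshold. In the Lgr5 comparison 22 values of named genes moved by at least 0.25 and 341 moved less. Of 22 list medians in the Lgr5 sort, 19 kept their sign under 3 other settings of scaling and probe choice; lymphocyte, myeloid and BMP lists did not. Dim genes are limited by array background.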

Other observations

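The comparisons and tests in this part were chosen after the result was seen. Some gene groups differed between the hybridizations in every EphB2 group. Enteroendocrine genes were lower in the second hybridization by a median of -0.73 in high, -0.74 in medium and -0.57 in low cells, and tuft genes by -0.38, -0.57 and -0.52. Vim, an intermediate filament gene, had an SD between replicates of 0.93, 1.21 and 0.78 in high, medium and low cells. Mitosis and replication genes differed mostly in low cells, by -0.95 and -0.80, against 0.14 and 0.03 in high cells. The stem cell list followed, with -0.65 in low and 0.22 in high cells.

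MHC class II genes had array medians of 11.20 and 10.18 in medium, 11.71 and 11.08 in high and 11.50 and 11.79 in low cells. Between high and medium cells the list did not shift (camera, adjusted p = 0.275), and limma called 0 of 7 genes (1 at an unadjusted p below 0.05). Of the erythrocyte list, 4 genes were measured, too few for a test, and limma called 0 of them between high and low (1 at an unadjusted p below 0.05), with Epb42, named after its value was seen, nearest (1.32, adjusted p = 0.0681); the highest value on any array was 6.05.

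Leaving controls aside, 43 probe sets had both Lgr5 arrays outside the range of all 6 EphB2 arrays by at least 1 log2 unit, 37 higher and 6 lower, with 5 of immunoglobulin kappa genes. The largest gaps were 8.12, 7.91 and 5.87 in probe sets without a gene name, then 5.66 for the alpha-defensin Defa31, which was named after its value was seen. Of 18 other bright probe sets of the same genes, 94.4% stayed within 1 of the EphB2 range, so sequence or probe differences may account for part of it. Within 1 is not the same as inside the range, so this share cannot exclude smaller shifts of whole genes. The test covered 10 genes, none of them with these 4 gaps, and left out each gene's most shifted probe set by choice. P2rx7 and Sntb1 had 2 probe sets each outside the range, and the second of each (1.08 and 1.04) was too dim to be among the 18. Arhgap9 also had 2 (-1.29 and -1.25), and its further one at -0.95 counted as within. The further Ceacam10 probe set, at 0.94, counted as within too. For these genes the probe sets moved together. Those of Ints6l (0.59) and Snx19 (-0.49 and -0.14) also lay outside the range, in the direction of the gene's most shifted probe set. So did a Snhg14 (0.16) and a Ddx39b probe set (0.11), with others of these genes inside the range. A Uqcrq probe set lay outside in the other direction (-0.03). The rest of the 18, such as those of Gtpbp4 and Sf3b5, lay inside the range. The EphB2 hybridizations parted by at least 1 in 15 probe sets. That count set arrays of all EphB2 levels against each other, and the 43 came from both Lgr5 arrays against all 6 EphB2 arrays. The 2 counts are therefore not on the same footing. The Lgr5 arrays form a hybridization of their own, from reporter mice, so hybridization and mice cannot be told apart.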
